A study of Mus musculus with 4 samples.

How the data were processed

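LSD1 ChIP-seq libraries and inputs were made from C2C12 cells at day 2 and day 5 of differentiation, 4 libraries in all and 1 per group. Groups were taken from the sample titles. Per the labels' protocols, cells grown in 10% fetal serum and 25 mM glucose were switched to 2% horse serum, crosslinked with formaldehyde and disuccinimidyl glutarate, and sonicated in 2 steps. Libraries were amplified for 8 to 10 cycles to fragments of about 170 to 500 bp and sequenced on Illumina NextSeq instruments, per the labels' protocols. The submitters' processing notes name Bowtie2, deepTools and the build mm9, without versions or roles.

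The authors deposited 1 list of peaks for each LSD1 library. Per the file headers, peaks were called with MACS run in Galaxy. The MACS version, its cutoff, the handling of duplicate reads and whether the input served as control are not given in the sources used here. The 2 lists come from single libraries, with no pooling. Besides a position, each line gives the peak score, which the authors deposited as the peak caller gave it. The scale of this score is not stated in the file headers. Its lowest value was 50 in both lists and its highest 3100 at day 2 and 2608 at day 5, and it was used within each list, for ranks, deciles, limits, medians and quartiles and the values of named peaks. The limit at the day 2 median was the exception, since it was applied to both lists. A peak's position and width are the other deposited values, in bp. Peak number and width in such lists depend on read depth, fragment length and the caller's settings, which were not analysed here, so a single pair of lists does not separate them from occupancy. Intervals cover counting error only.

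Peak starts were counted from 0 in the deposited lists and are printed counted from 1. No peak was duplicated and no peaks of 1 list overlapped each other. The end of the last peak on chromosome 1 was 197068228 at day 2. The gene table at hand belongs to another assembly, GRCm38.p6, and no coordinates were converted. For that reason the planned shares of peaks at promoters, the genes with a promoter peak for 20 gene lists and the shares of 15 motifs were not run, and regions were named by position. The rule for named regions, written before the data were examined, took from each list the 10 peaks of highest score (ties by width, then position), the 10 widest peaks, the 10 windows of 100 kb with the most peaks, and the 5 windows of 1 Mb with the largest difference in share of the list in each direction. Peaks were put into windows by their midpoint. The strongest peaks of a single day were added after the values were seen.

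Peaks were called shared when they overlapped by at least 1 bp. Shares have Wilson 95% intervals and medians have binomial order-statistic intervals. The shares given by random placement came from 1000 circular shifts of the day 5 peaks within the span of peaks on each chromosome, and, added later, from 1000 shifts of each peak by 10 to 100 kb. The number of day 2 peaks with a day 5 peak, called kept peaks in the closing section, was compared with that given by the score alone. For this, peaks were drawn 1000 times at the kept share of their bin among 50 bins of the day 2 score rank, or among 25 score bins each divided into 4 by width, and 1 Mb windows with at least 5 day 2 peaks were used. Alternatives covered the score limit, merging of peaks less than 1 kb apart, autosomes only, an overlap of at least 50% of both peaks, a distance of up to 1 kb, equal list lengths, and covered length in place of peak number. Overlap counting was tested on simulated data made from the 44039 day 2 positions. Of all these positions, 30.0% were planted as shared and 30.0% were found shared. The planted peaks were narrower copies centred on day 2 peaks, so partial overlaps at peak edges were not tested. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.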

Results

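The occupancy of LSD1 on chromatin was mapped by ChIP-seq in C2C12 cells at 2 stages of myogenic differentiation. C2C12 is a mouse myoblast line that leaves the cell cycle and fuses into multinucleated myotubes when serum is reduced. LSD1, encoded by Kdm1a, is a nuclear enzyme that removes methyl groups from lysines of histone H3 and acts in repressor complexes with CoREST and histone deacetylases. Cells were sampled 48 h (day 2, differentiating) and 120 h (day 5, differentiated) after the change to 2% horse serum. The series holds 4 libraries, an LSD1 precipitate and an input at each day, with 1 library per group. No group had a replicate, so no difference between the days could be set against a replicate error and no p-value is given. Comparisons with random shifts or draws concern which peaks of these 2 lists overlap and leave out the spread between cultures. The intervals below are 95% intervals that cover counting error only, and they treat peaks as independent, which neighbouring peaks are not. The data analysed were the 2 peak lists deposited for the LSD1 libraries, in mm9 coordinates. Read totals and the input libraries were not analysed here, so the depth behind the peaks is unknown, and a count of peaks that differs can follow depth as well as occupancy. No gene annotation of mm9 was used here, so regions are given by position and not by gene.

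LSD1 peaks were more numerous and broader at day 2 than at day 5. The day 2 list held 44039 peaks and the day 5 list 17446, a ratio of 2.52. The median peak was 663 bp wide at day 2 (95% interval of the median 660 to 667) and 331 bp at day 5 (328 to 333). The middle of the distribution ran from 507 to 932 bp (quartiles) at day 2 and from 253 to 441 bp at day 5. Peaks together covered 34.1 Mb at day 2 and 6.54 Mb at day 5, a ratio of 5.21. Peaks of at least 2000 bp numbered 664 at day 2, or 1.51% of the list, and 3 at day 5. The peak score, which is the authors' own value from the peak caller and is used here within a list except for 1 limit applied to both, had a median of 104 at day 2 and ran from 50 to 3100. At day 5 it had a median of 72.2 and ran from 50 to 2608. Raising the score limit to the day 2 median in both lists moved the ratio of peak numbers to 5.19, although scores of separate peak calls need not be on 1 scale.

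**Figure D1:**
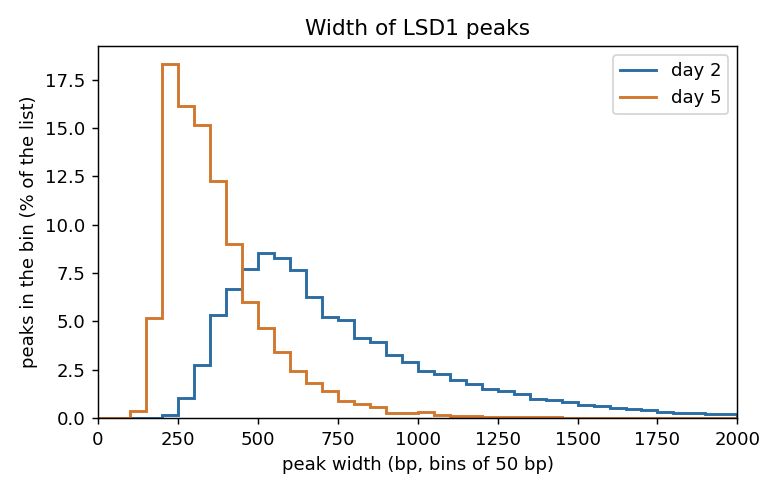
Histogram of peak width in bp (bins of 50 bp, widths to 2000 bp) as a percentage of each list, with the day 2 list in blue and the day 5 list in orange, 1 library each. The day 5 distribution lies to the left of the day 2 distribution, with medians of 331 and 663 bp.

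By an overlap of at least 1 bp, most sites occupied by LSD1 at day 5 were also occupied at day 2. Most day 2 sites had no day 5 peak. Of the day 5 peaks, 15013 (86.1%, Wilson interval 85.5 to 86.6) overlapped a day 2 peak by at least 1 bp. Of the day 2 peaks, 13393 (30.4%, 30.0 to 30.8) overlapped a day 5 peak, leaving 30646 in the day 2 list alone. The day 5 list alone held 2433 peaks, 13.9% of it. When the day 5 peaks were moved together by a random distance along each chromosome, in 1000 repeats, on average 2.16% of them met a day 2 peak (range 1.73 to 2.80%), and 0.821% of day 2 peaks met a day 5 peak (0.663 to 1.04%). Shifts of only 10 to 100 kb gave 5.49% and 2.17%. The overlap of the lists was therefore far above that of placement at random, both along whole chromosomes and within the same neighbourhoods.

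At sites in both lists, the day 5 peak lay inside a broader day 2 peak. The lists formed 15073 overlapping pairs. The day 5 peak was the narrower one in 14954 pairs (99.2%, 99.1 to 99.3), and the median ratio of day 2 to day 5 width was 2.59 (quartiles 1.88 to 3.77). In 13326 pairs (88.4%) the day 5 peak lay wholly within the day 2 peak. The midpoints of a pair were a median of 123 bp apart (quartiles 51 to 255 bp). Of the day 2 peaks with a partner, 1517 (11.3%) held at least 2 separate day 5 peaks, and 4 was the largest number in 1 peak. Because of this difference in width, the shared share depended on the definition of overlap. With overlap required over at least 50% of both peaks, 4250 peaks of each list were shared, which is 24.4% of the day 5 list and 9.65% of the day 2 list.

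Shared sites carried the higher scores in both lists. Day 2 peaks with a day 5 partner had a median score of 213 (quartiles 125 to 356) and a median width of 918 bp, against 84.6 (62.4 to 131) and 593 bp for day 2 peaks without one. Day 5 peaks with a day 2 partner had a median score of 77 (59.8 to 110) and a median width of 350 bp, against 57.1 (52.7 to 65.9) and 238 bp for those without one. From the lowest to the highest decile of the day 2 list by score, the share with a day 5 peak went from 5.97% (5.31 to 6.71) to 85.9% (84.8 to 86.9), and it was higher in each decile than in the one below. Among the top decile of day 5 peaks, 1742 of 1745 had a day 2 partner (99.8%, 99.5 to 99.9), and in the lowest decile 68.2% had one (66.0 to 70.4). The top decile of the day 2 list still held 623 peaks with no day 5 peak, 14.1% of it (13.1 to 15.2). When the lists were made equally long by taking the 17446 day 2 peaks of highest score, 56.2% of these had a day 5 peak and 65.3% of day 5 peaks had one of these.

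**Figure D2:**
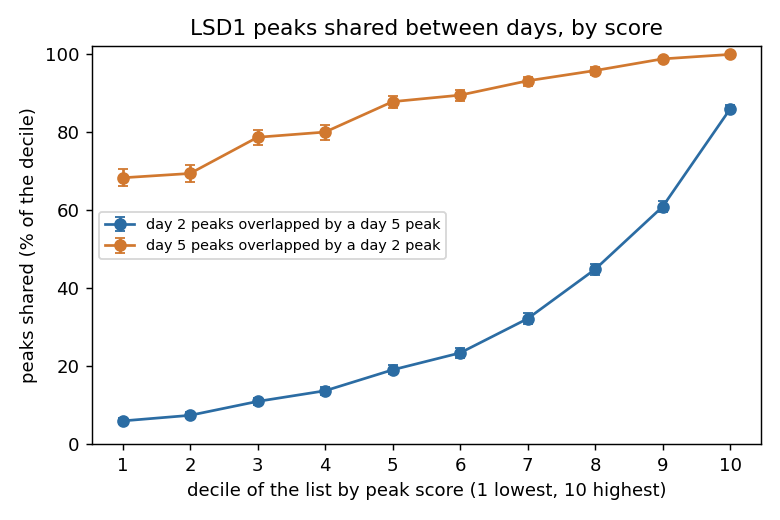
Percentage of peaks overlapped by a peak of the other day (vertical axis) in each decile of a list by peak score (horizontal axis, 1 lowest to 10 highest), with day 2 peaks in blue and day 5 peaks in orange. Bars are Wilson 95% intervals, which cover counting error only. Day 2 peaks go from 5.97% to 85.9% and day 5 peaks from 68.2% to 99.8%.

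The strongest LSD1 sites were largely common to both days. Each of the 10 peaks of highest score at day 2 had a day 5 peak, each of the 10 at day 5 had a day 2 peak, and 6 sites were among the 10 highest of both lists. The first 3 places were held by the same sites in each list. On chromosome 2 the site spanned positions 92022805 to 92024612 at day 2 (score 3100) and 92023057 to 92024168 at day 5 (score 2608). On chromosome 8 it spanned 89995856 to 89997561 (3100) and 89996299 to 89997428 (2201), and on chromosome 3 it spanned 94216285 to 94217792 (3100) and 94216462 to 94217575 (1352). The value of 3100 was shared by these 3 day 2 peaks and was the highest in the list, so their order was set by width. Whether 3100 is a ceiling of the score is not known here. The other sites among the 10 highest of both lists were chromosome 4, 133368541 to 133370576 (day 2 score 2642, day 5 score 692), chromosome 4, 135732788 to 135734395 (1918 and 841), and chromosome 11, 116441667 to 116443429 (2107 and 728). The other 4 high-scoring day 2 sites lay on chromosome 17 from 23835846 (score 2198), chromosome 11 from 59119569 (1958), chromosome 5 from 113643487 (1924) and chromosome 15 from 88581196 (1905). The other 4 at day 5 lay on chromosome 2 from 119372556 (830), chromosome 6 from 125165308 (729), chromosome 1 from 99557216 (700) and chromosome 3 from 51143567 (692).

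The highest-scoring sites found on a single day lay on several chromosomes. These sites were chosen after their values were seen. The highest-scoring day 2 peaks with no day 5 peak lay on chromosome 12 at 74576982 to 74578150 (score 761, place 473 of the 44039 day 2 peaks), chromosome 8 at 72990102 to 72992498 (743, place 517) and chromosome 6 at 136994446 to 136995960 (737, place 538). The highest-scoring day 5 peaks with no day 2 peak on assembled chromosomes lay on chromosome 15 at 38360967 to 38361730 (165, place 1514 of the 17446 day 5 peaks), chromosome 17 at 72952367 to 72952851 (159, place 1655) and chromosome 12 at 112709373 to 112709897 (146, place 2029).

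The widest LSD1 regions at day 2 were concentrated on chromosome 15, which held 5 of the 10 widest peaks, and 3 of the 10 widest at day 5 were on chromosome 8. All of these wide peaks had a peak on the other day. The widest day 2 peak other than the 2 described next was on chromosome 8 at 86724278 to 86729006, 4729 bp wide, and 3 day 5 peaks with a summed width of 2073 bp lay in it. On chromosome 15 the day 2 peak at 101197590 to 101202100 was 4511 bp wide, and that at 7759678 to 7764143 was 4466 bp wide. The widest such day 5 peak lay on chromosome 8 at 83402592 to 83404768 and was 2177 bp wide. In each list 2 peaks exceeded 5 kb, at the same places. The first, on chromosome 11 at 3038157 to 3048980, was 10824 bp wide at day 2 and 8528 bp at day 5. The second, on chromosome 17 at 39979816 to 39985821, was 6006 bp wide at day 2 and 5917 bp at day 5. At both places the widths of the days were closer than in the median overlapping pair, where the ratio was 2.59. Whether reads can be placed uniquely at these 2 places was not analysed here, so they need not be sites of LSD1.

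LSD1 peaks were sparse on chromosome X and dense on chromosomes 11, 15 and 19 at both days. Copy number and the placing of reads were not analysed here, so these densities need not follow LSD1 alone. Chromosome X carried 547 day 2 peaks (1.24% of the list, 1.14 to 1.35) and 118 day 5 peaks (0.676%, 0.565 to 0.809), although it made up 6.27% of the length spanned by peaks. This was 3.41 peaks per Mb at day 2 and 0.736 at day 5. The 19 autosomes ranged from 13.2 to 29.9 per Mb at day 2 (median 18.1) and from 5.27 to 12.3 at day 5 (median 6.63). Chromosome 11 had the highest density at day 2 (29.9 per Mb) and chromosome 15 at day 5 (12.3 per Mb, against 24.7 at day 2). Chromosome 15 took 5.62% of day 2 peaks (5.40 to 5.83) and 7.04% of day 5 peaks (6.67 to 7.43). Of the day 2 peaks on chromosome 15, 39.0% had a day 5 peak (37.1 to 40.9), the highest of the autosomes, the other 18 of which lay between 26.2% on chromosome 7 and 32.4% on chromosome 10. On chromosome X, 14.8% had one (12.1 to 18.0). Neither list held a peak on chromosome Y or on mitochondrial DNA. Unplaced sequences carried 33 day 2 and 13 day 5 peaks.

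**Figure D3:**
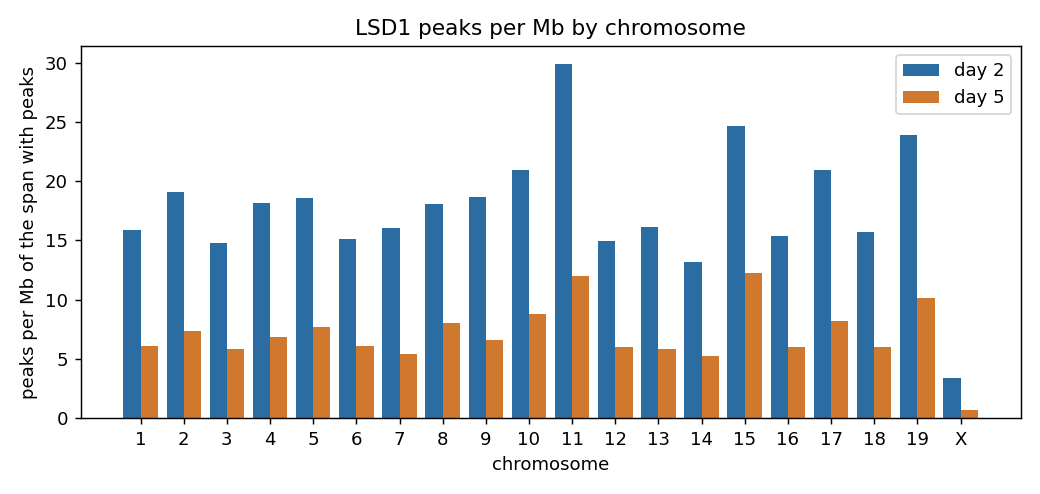
LSD1 peaks per Mb on each chromosome (the vertical axis starts at 0, and length is the span between the first and last peak), with day 2 in blue and day 5 in orange, 1 library each. Chromosome X stands at 3.41 and 0.736 peaks per Mb, below the lowest autosome (13.2 and 5.27).

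Dense groups of LSD1 peaks recurred at both days in a few 100 kb windows. Day 2 peaks occupied 12066 such windows and day 5 peaks 7947, of which 245 had no day 2 peak. At least 10 peaks lay in 691 windows at day 2 and in 39 at day 5. The fullest day 2 window was on chromosome 1 at 137500001 to 137600000, with 27 day 2 peaks and 15 day 5 peaks, followed by chromosome 10 at 80800001 to 80900000 (26 and 8) and chromosome 14 at 26300001 to 26400000 (24 and 9). The fullest day 5 windows were on chromosome 13 at 23600001 to 23700000 (17 day 5 and 18 day 2 peaks), chromosome 15 at 78600001 to 78700000 (17 and 22) and chromosome 8 at 86700001 to 86800000 (16 and 15). Among the 10 fullest windows of each list, 3 were common: that on chromosome 1, that on chromosome 15 and chromosome 2 at 30500001 to 30600000 (21 day 2 and 13 day 5 peaks).

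The relative weight of some megabase regions differed between the lists. The 1 Mb window whose share of the list at day 5 most exceeded its share at day 2 was chromosome 8 from 86 to 87 Mb, with 69 day 2 peaks (0.157% of the list, 0.124 to 0.198) and 63 day 5 peaks (0.361%, 0.282 to 0.462). It was followed by chromosome 15 from 78 to 79 Mb (78 and 57 peaks), chromosome 13 from 23 to 24 Mb (57 and 40), chromosome 15 from 38 to 39 Mb (58 and 40) and chromosome 15 from 79 to 80 Mb (89 and 52). In the window on chromosome 8, 59.4% of day 2 peaks had a day 5 peak, against 30.4% over the whole list. Part of this contrast is score: the scores of its 69 day 2 peaks gave 29.0 with a day 5 peak, and 41 had one. The windows with the largest difference in the other direction were chromosome 7 from 96 to 97 Mb (35 day 2 and 4 day 5 peaks), chromosome 7 from 133 to 134 Mb (44 and 8), chromosome 1 from 136 to 137 Mb (49 and 10), chromosome 1 from 135 to 136 Mb (64 and 16) and chromosome 7 from 134 to 135 Mb (70 and 19). On chromosome 7 from 96 to 97 Mb, 4 day 2 peaks had a day 5 peak where scores gave 7.42. From 133 to 134 Mb it was 5 where scores gave 9.09, and from 134 to 135 Mb 18 where scores gave 19.8. On chromosome 1 it was 6 against 12.6 from 136 to 137 Mb and 16 against 20.6 from 135 to 136 Mb. All lay below the number from score, chromosome 7 from 134 to 135 Mb only slightly. For chromosome 7 from 96 to 97 Mb the share was 0.0795% at day 2 (0.0572 to 0.111) and 0.0229% at day 5 (0.00892 to 0.0589), so the intervals overlapped slightly. In the other windows of this direction they overlapped by more, as on chromosome 7 from 134 to 135 Mb (0.126 to 0.201 and 0.0697 to 0.170). Intervals also overlapped on chromosome 15 from 38 to 39 Mb and from 79 to 80 Mb. They were apart on chromosome 8 from 86 to 87 Mb, chromosome 15 from 78 to 79 Mb and chromosome 13 from 23 to 24 Mb. These windows were picked as extremes of all windows, and their intervals do not allow for that choice.

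**Figure D4:**
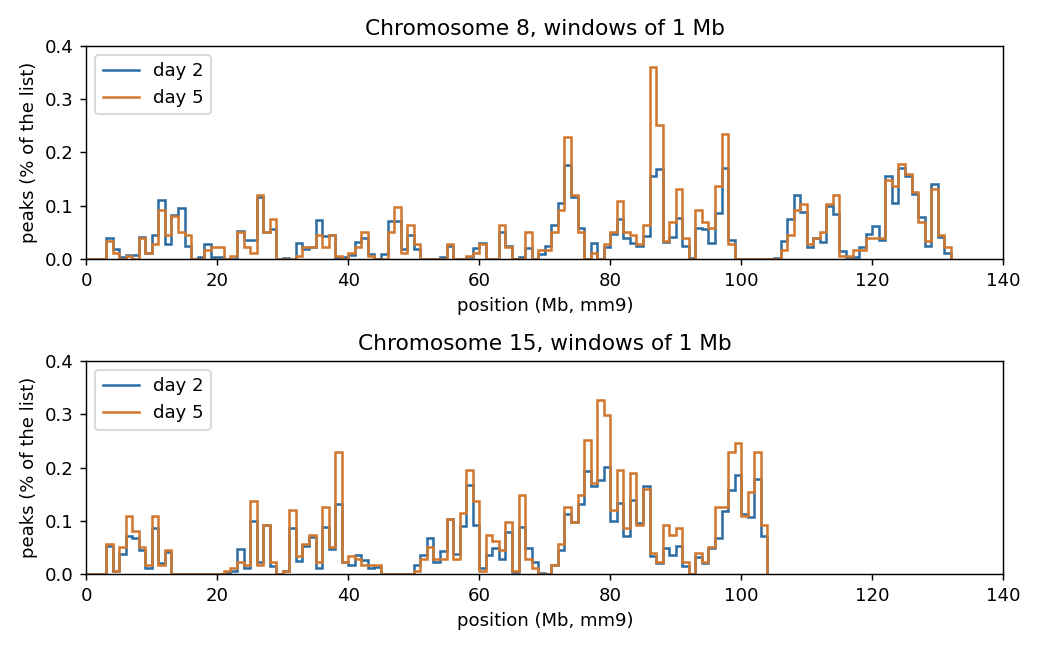
Peaks in each 1 Mb window of chromosomes 8 (top) and 15 (bottom) as a percentage of the whole list (vertical axis) along the chromosome in Mb of mm9 (horizontal axis), with day 2 in blue and day 5 in orange, 1 library each. The day 5 line reaches 0.361% at 86 to 87 Mb of chromosome 8, where the day 2 line is at 0.157%.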

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

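Of 52 alternatives for 16 values, 16 stayed within their interval (counts and covered lengths within 1.5 times), 36 moved and none was labelled reversed. A count, width, length or share cannot change sign, so only the score differences could have reversed in sign. The shares of shared peaks did cross 50%. Under an overlap of at least 50% of both peaks, the day 5 share fell from 86.1% to 24.4%. At equal list lengths the day 2 share rose from 30.4% to 56.2%. In the alternatives that recomputed peak number, width or covered length, day 2 had the higher value of each that was recomputed. Equal list lengths set the number of peaks alike by construction. Splitting each list at its own median score kept the ratio of peak numbers at 2.52, also by construction. The alternatives that recomputed none of these values did not bear on them. With the upper part of each list by score (split at its median), peaks numbered 22020 at day 2 and 8723 at day 5, median widths were 903 and 423 bp, covered lengths 22.0 and 4.09 Mb, and 31.8% of day 2 peaks were shared. Chromosome X then took 0.763% and 0.470% of the lists and chromosome 15 took 5.99% and 8.21%. With scores at or above the day 2 median, 22020 and 4246 peaks were left, with median widths of 903 and 524 bp and covered lengths of 22.0 and 2.41 Mb. Merging peaks less than 1 kb apart gave median widths of 718 and 354 bp. By covered length, chromosome X took 1.02% and 0.549%, and chromosome 15 took 6.67% and 8.82%. An overlap of at least 50% of both peaks left 9.65% of day 2 and 24.4% of day 5 peaks shared, and the median score of shared peaks minus that of the rest was then 77.9 at day 2 (128.75 before) and 31.1 at day 5 (19.9 before). A distance of up to 1 kb gave 35.6% and 89.0%, and equal list lengths gave 56.2% and 65.3%. The drop under the 50% rule follows from its construction, since the day 2 peak is a median of 2.59 times as wide as its partner; the cause of the other moves was not tested. Chosen after seeing the data, sites in both lists had median widths of 918 and 350 bp and covered 13.7 Mb at day 2 and 5.91 Mb at day 5, a ratio of 2.32 against 5.21 for the whole lists, and leaving out peaks wider than 5 kb left 44037 and 17444. The planned promoter, gene list and motif analyses were not run, and with 1 library per group there was no replicate to leave out.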

Other observations

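Long stretches of several chromosomes held no LSD1 peak on either day. On the autosomes the longest were on chromosome 15 from 12778425 to 21685883 (8.91 Mb), chromosome 6 from 73230068 to 81873336 (8.64 Mb), chromosome 7 from 39056650 to 46704527 (7.65 Mb) and chromosome 8 from 98412720 to 105308742 (6.90 Mb). On chromosome X the longest ran from 109450495 to 126283639 (16.8 Mb). Whether reads can be placed in these intervals was not analysed here. The chromosome 11 peak at 3038157 to 3048980 had a score of 194 at day 2, at place 10609 of its list, and a score of 480 at day 5, at place 46. Whether reads can be placed uniquely in this peak was not analysed either, so the change in place need not reflect LSD1. The highest-scoring day 5 peak without a day 2 partner (score 233) lay on an unplaced sequence.

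Chosen after the result was seen were the day 2 partners of the strongest day 5 peaks, the scan of 20 Mb stretches, and the comparisons of chromosome 8 from 79 to 99 Mb and of the rest of chromosome 15, the last 2 with no prediction written. All rest on 1 library per day, and their draws treat neighbouring peaks as independent.

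The day 5 list was shorter and its peaks narrower. Other, narrower sites at day 5 were argued against, because the day 5 peak was the narrower one in 99.2% of the overlapping pairs. A weaker sampling of the same sites at day 5 may account for the shorter list: 0.172% of the top decile of day 5 peaks lacked a day 2 peak, and the share of day 2 peaks kept was higher in each decile of the score than in the one below. Still, 623 peaks in the top decile of the day 2 list (14.1%) had no day 5 peak. At equal list lengths 56.2% of day 2 peaks and 65.3% of day 5 peaks were shared. Whether weaker sampling gives these values was not tested. A shorter list of narrower peaks could come from a shallower library, a less efficient precipitation, shorter fragments or other caller settings. It could also come from less LSD1 on the same sites in differentiated cells. None of these was tested, and no value here tells them apart.

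A larger part of the day 2 peaks was kept at day 5 in a stretch of chromosome 8 and along chromosome 15 than their scores gave. In the 1 Mb window at 86 to 87 Mb of chromosome 8 the excess was 11.99 kept peaks (41 against 29.0), a value that 38 of 1000 draws by score reached somewhere in the genome, and over 20 Mb the highest excess was 59.4 kept peaks, at 71 to 91 Mb of chromosome 15 (highest of 1000 draws 46.9). Both argue against chance scatter of single peaks, the first narrowly, and matching width as well left an excess of 58.3 (highest draw 50.4), which argues against wider day 2 peaks as the whole cause. The stretch at 71 to 91 Mb kept 41.3% of its 900 day 2 peaks where scores gave 34.7%. The excess is a count, so it tends to be larger where peaks are many. The excess was not particular to that stretch: the rest of chromosome 15 kept 37.6% of 1573 peaks (35.3 to 40.1) where scores gave 33.4% and scores and width 34.0% (highest draw 37.3%). A copy number or background gain over a stretch of several Mb is a candidate explanation, since 10 of the 10 windows within 5 Mb of that chromosome 8 window (100%) kept more peaks than their scores gave, against 48.0% of the 1722 windows of the genome. Because day 2 scores were matched, a gain would bear on this most directly if it differed between the days. A regional difference in LSD1 would also give such a run of windows, so the run does not tell these apart. On chromosome 8 from 79 to 99 Mb, a stretch chosen after the values were seen, 45.2% of peaks were kept (41.0 to 49.4) where scores gave 34.4%, against 27.7% before it and 29.4% after it, where scores gave 29.5% (middle 95% of draws 27.3 to 32.1) and 31.1% (28.5 to 33.8). Part of the contrast with the flanks is therefore score. The excess in this chromosome 8 stretch was 57.8 kept peaks, from 538 day 2 peaks. Its kept share thus stood further above that from score than at 71 to 91 Mb of chromosome 15. The input libraries, which would show copy number, were not analysed here, and regional differences in LSD1 between the stages stay open and untested.

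Chromosome X kept fewer of its day 2 peaks than the autosomes, 14.8% against 30.6%. Their lower scores (median 79.2 against 105) gave an expected 19.8%, and the middle 95% of 1000 draws ran from 16.8 to 22.9%, so score argues for part of the gap but not for all of it. Matching width as well as score also gave 19.8%, and 1 of 1000 draws was as low as the observed share, which argues against narrower peaks as the cause of the rest. A lower copy number or background on chromosome X may add to the gap and was not tested. Because day 2 scores were matched, it would bear on the rest of the gap most directly if it differed between the days. Of the 20 chromosomes, 4 lay outside the middle 95% of their draws, where 1 would be expected: X and 15, and, only just below it, chromosomes 4 (29.1% kept, lower limit 29.2%) and 9 (27.7%, lower limit 27.9%).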
